A study of Rattus norvegicus with 484 samples.

How the data were processed

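Each array compared RNA of 1 rat, labelled with Cy5, with a pool of vehicle rats of the same tissue and day, labelled with Cy3. Per the labels of 405 samples, cRNA was made by reverse transcription and in vitro transcription and coupled to dye in a separate step. The table deposited by the authors holds log10 ratios for 23653 probes on 484 arrays. How they were normalised, their scale and the direction of the ratio are not stated in the labels. Scale and direction were inferred from the values, which centre on 0 and are limited to -2 and 2, the bound that a 100-fold limit gives on a log10 scale, and from the channels. Ratios were taken as rat over pool and multiplied by 3.32 to give log2 values. If the base were another, all fold changes would scale together and the tests would stand. 0.91% of the values were missing and 699 (0.006%) lay at the limit. Intensities and background were not used here, so the number of arrays limits the precision.

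Probes were named from the platform table and matched by gene identifier to the rat gene table: 15260 probes named 1 gene, 17 named several and 8376 had no name. Probes of a gene were averaged, which gave 10210 genes (3260 with more than 1 probe). With the probes that named no single gene they made 18603 features. Per comparison, features with a value on at least 80% of the arrays were tested. Probes of the same gene pointed in both directions for 16 of 181 multi-probe pairs of a named gene and a comparison, and beyond 2 SE in 3.

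Groups were tissue, compound and dose. For soleus, quad and liver a linear model with 1 mean per compound and day was fitted with limma 3.58.1 in R 4.3.3. Each compound was set against vehicle within days, and the days were averaged with equal weight. The PPARA agonist mean averages fenofibrate, bezafibrate and Wy-14643. Differences between compounds, a slope per day and the difference between soleus and quad were contrasts of the same kind. EDL had no arrays of single vehicle rats, so its ratios were tested against 0, and the dose pair of rosiglitazone on day 4 was compared directly. P values were two-sided, from limma's moderated test, adjusted by Benjamini-Hochberg within each comparison at 0.05. Gene lists were fixed in advance and tested with limma's camera on moderated statistics, with a preset correlation of 0.01 and again with the correlation estimated from the residuals, adjusted over the lists of a comparison. Other steps used statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

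The groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the first 5 of the 10 largest rises and of the 10 largest falls among named genes that passed and had the same sign on each day, up to 4 passing members of each list with the smallest adjusted p, and a fixed set of PPARA targets and muscle genes. Skipping symbols that only number a locus was added later. The rule for arrays in doubt was written after the arrays were seen: a median absolute deviation above 3 times the median of the tissue, or a median of another tissue's marker genes more than 2 log2 units above the arrays of the same tissue and day.

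The procedure was tested on simulated data with 200 changed genes. At a change of 0.26 log2 units it recovered 76.5% in soleus, 95.6% in quad, 91.2% in liver and 60.3% for the difference between soleus and quad. There were 8, 11, 11 and 7 false calls in the same order, and at 1 log2 unit 100% was recovered in each. The simulated noise was normal and independent between genes and arrays, without the wide arrays of the real data. Splits of the real arrays into random groups called up to 7258 for fenofibrate in quad, so these false calls do not carry over. Alternatives were subtracting array medians, scaling arrays to one spread, array quality weights, complete values only, leaving out each day, the ratio to the pool in place of single vehicle rats, the rat as a block, and other compounds as the EDL reference. Leaving out the doubted arrays, together and singly, was added after the data were seen. The mean of each tissue, compound, dose and day was subtracted to see whether rat numbers pair the arrays. Soleus and quad arrays with the same rat number then correlated at a median of 0.246 over 111 rats. The median was -0.069 for other numbers of the same compound and day. Subtracting the mean of few rats itself pushes that value below 0. Since compounds share vehicle arrays, overlaps were set beside 10 simulated sets with shared controls and beside 10 random halvings of the vehicle arrays. For comparisons of groups, 100 splits of the arrays into groups of the same sizes were drawn within tissue and day, the real one included, and 35 for the EDL dose pair.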

Results

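RNA from soleus, quad and liver of rats, and from a muscle that the labels call EDL, was measured on 484 2-colour arrays, 54 of them of EDL. The names quad and EDL are used as the labels give them. On every array the Cy5 channel held RNA of 1 rat and the Cy3 channel held a pool of vehicle rats of the same tissue and day. The rats had received fenofibrate or bezafibrate (both fibrates), Wy-14643 (a PPARA agonist), rosiglitazone (a PPARG agonist), retinoic acid, or vehicle, and were sampled on days 2 to 6. The EDL arrays covered days 3 to 6 with Wy-14643 and retinoic acid, and days 4 to 6 with the fibrates and the lower rosiglitazone dose. Doses are given as mkd, as in the labels: 400 for fenofibrate, 250 for bezafibrate, 100 for Wy-14643, 100 for rosiglitazone and 25 for retinoic acid. Soleus had 19 fenofibrate, 20 bezafibrate, 18 Wy-14643, 20 rosiglitazone, 20 retinoic acid and 35 vehicle arrays. Quad had 18, 20, 16, 16, 18 and 63 in the same order, and liver had 14, 15, 15, 15, 15 and 73. EDL had lower doses and no arrays of single vehicle rats: 9 arrays of fenofibrate at 50, 9 of bezafibrate at 25, 12 of Wy-14643 at 10, 9 of rosiglitazone at 10, 11 of retinoic acid at 2.5, and 4 of rosiglitazone at 100 on day 4.

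The values are ratios of a rat to its pool, so a treated rat was compared with the single vehicle rats of its tissue and day, and the days were averaged with equal weight. Effects are log2 fold changes with their SE. For arrays the number of rats limits the precision. The median SE of the PPARA agonist mean was 0.058 in soleus, 0.037 in quad and 0.036 in liver. A rule made after the arrays were seen put 9 of them in doubt, either for a spread more than 3 times the median of their tissue or for marker genes of another tissue. They were vehicle rats 1022, 1034 and 1061 in soleus, vehicle rats 1042 and 1068, fenofibrate rat 1157, bezafibrate rat 1256 and retinoic acid rat 1321 in quad, and rosiglitazone rat 1376 in liver. They stayed in every comparison, and the count of calls of each comparison that holds any of them is also given without them.

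Across the 3 PPARA agonists, soleus responded with higher expression of genes that bring fatty acids into mitochondria and oxidise them. Acot1, an acyl-CoA thioesterase and a classic PPARA target, rose by 1.63 ± 0.16 (SE, n = 57 treated and 35 vehicle arrays), a 3.09-fold change seen in 57 of 57 treated arrays. Pdk4, the kinase that shuts pyruvate out of oxidation, rose by 0.71 ± 0.09 in 54 of 57 arrays, and Angptl4, an inhibitor of lipoprotein lipase, by 0.89 ± 0.12 in 53 of 57. The other largest rises were in Pik3c2g (1.14 ± 0.14), the clock gene Bmal1 (1.06 ± 0.21) and Tmem171 (0.97 ± 0.14). Bmal1 ran from -1.6 to 3.28 over the treated arrays. It was also higher with rosiglitazone, in 16 of 16 quad arrays and 12 of 15 liver arrays, so a rise of Bmal1 was not particular to the PPARA agonists. The largest falls were in Chac1 (-0.52 ± 0.15), Ier3 (-0.50 ± 0.08), Map2k6 (-0.49 ± 0.12), Hpn (-0.43 ± 0.12) and C9h6orf132 (-0.35 ± 0.09).

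Of the 16 measured genes of mitochondrial beta-oxidation in soleus, 13 rose and 3 did not pass (14 rose when adjusted over the list alone). Examples are Acot2 (0.76 ± 0.07), Eci1 (0.43 ± 0.07), Cpt2 (0.34 ± 0.07) and Hadha, the alpha subunit of the trifunctional protein (0.31 ± 0.05). The list moved up against all other genes with limma's camera (adjusted p = 2.5e-28, and adjusted p = 6.8e-08 with an estimated correlation). Fuel switching and uncoupling had 3 of 10 genes higher (4 adjusted over the list alone), among them Ucp3 (0.49 ± 0.07), with adjusted p = 0.0078 with an estimated correlation. Fatty acid uptake and lipid droplets had 5 of 13 higher (8 adjusted over the list alone), led by the transporter Cd36 (0.37 ± 0.07) and the lipase Lipe (0.27 ± 0.06), with adjusted p = 0.028 with an estimated correlation. Peroxisomal beta-oxidation had 3 of 18 higher, Ech1 (0.64 ± 0.06), Eci2 (0.41 ± 0.05) and Abcd3 (0.27 ± 0.07), and the same count adjusted over the list alone. That list was called with the preset correlation (adjusted p = 0.00027) but not otherwise (adjusted p = 0.49 with an estimated correlation). No oxidative phosphorylation gene passed over all genes and 10 of 20 did adjusted over the list alone (adjusted p = 0.57 with an estimated correlation). Ehhadh had 0.21 ± 0.11, Cyp4a1 -0.09 ± 0.11, Cpt1a 0.01 ± 0.03, Ppara -0.03 ± 0.05, Ppargc1a 0.15 ± 0.11 and the slow myosin Myh7 0.05 ± 0.05, none of which passed.

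In total 360 of 18365 genes and unnamed probes passed 5% in soleus (limma, Benjamini-Hochberg), 246 higher and 114 lower. Without the doubted arrays 418 passed. Single arrays and days moved the count: without vehicle rat 1022 it was 965 and without vehicle rat 1061 it was 182, and leaving out day 2, 3, 4, 5 or 6 gave 722, 599, 99, 89 or 231. The 9 fast fibre genes had a median of -0.49 with no gene called (1 lower adjusted over the list alone), and that list shifted lower only with the preset correlation (adjusted p = 0.57 with an estimated correlation). The fast myosin Myh4 varied widely between soleus arrays. Against the vehicle mean of their day, treated arrays ran from -3.87 to 3.53, with 26 of 53 on the side of the mean effect. Vehicle arrays had a mean ratio to the pool of -1.62 with an SD of 2.37 (n = 29). In quad 14 vehicle arrays had a value for it. Adipocyte markers had 3 of 11 higher (3 adjusted over the list alone), with a median of -0.04, a mean of 0.04 and a camera direction up that did not pass. Among these 3, Fabp4 (0.21 ± 0.06) did not pass without the doubted arrays (0.17). Hepatocyte markers had a median of -0.15 with none of 12 called. On vehicle rat 1034 they lay 4.56 log2 units above the other soleus arrays of its day, and the lists of acute phase genes (median -0.15) and bile acid genes (median -0.14) moved with them.

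**Figure D1:**
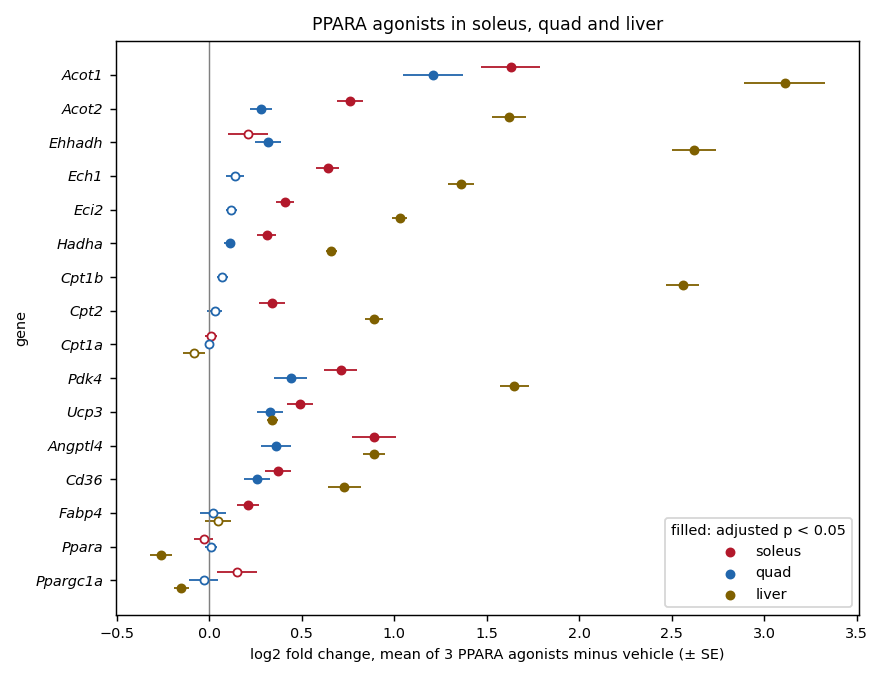
Log2 fold change of 16 genes for the mean of the 3 PPARA agonists against vehicle in soleus, quad and liver; points are estimates, bars are SE and filled points passed 5% over all genes. Acot1 lay at 1.63 in soleus, 1.21 in quad and 3.11 in liver, and Cpt1a passed in none of them. Cpt1b had too few values in soleus and is not drawn there.

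The agonists differed within soleus. Fenofibrate at 400 mkd raised 14 of 16 mitochondrial beta-oxidation genes (14 adjusted over the list alone; adjusted p = 2.1e-09 with an estimated correlation), with Acot1 at 2.14 ± 0.21 (n = 19), Acot2 at 1.12 ± 0.09, Acaa2 at 0.66 ± 0.10 and Hadha at 0.51 ± 0.06. It also raised 6 of 20 oxidative phosphorylation genes (16 adjusted over the list alone), such as Ndufa9 (0.22 ± 0.05) and Cyc1 (0.18 ± 0.05), a list call that was lost with adjusted p = 0.22 with an estimated correlation. Lower after fenofibrate were Dnase1l3 (-0.70 ± 0.17), Ccl21 (-0.65 ± 0.14), Cma1 (-0.60 ± 0.15) and 2 of 19 macrophage and leukocyte markers (6 adjusted over the list alone), Cd74 (-0.45 ± 0.10) and C1qa (-0.42 ± 0.11), with adjusted p = 0.26 with an estimated correlation. Bezafibrate at 250 mkd raised Acot1 by 1.09 ± 0.21 (n = 20), Angptl4 by 1.23 ± 0.16 and Pdk4 by 0.77 ± 0.11, and 3 of the 16 mitochondrial genes (9 adjusted over the list alone; adjusted p = 0.012 with an estimated correlation). Its largest rise was Rbp7, a retinol-binding protein (1.53 ± 0.15, higher in 19 of 20 arrays). Fabp4, a fatty acid-binding protein of adipocytes and capillary endothelium, rose by 0.60 ± 0.08, Bmal1 rose by 1.52 ± 0.27 and Per1, another clock gene, fell by 0.80 ± 0.17. Wy-14643 at 100 mkd raised Acot1 by 1.66 ± 0.22 (n = 18), Pik3c2g by 1.30 ± 0.18, Ech1 by 0.64 ± 0.08, Acot2 by 0.58 ± 0.09 and Hadha by 0.26 ± 0.06, and 5 of the 16 mitochondrial genes (11 adjusted over the list alone; adjusted p = 9.8e-07 with an estimated correlation).

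Fenofibrate called 612 genes and probes in soleus (1114 without the doubted arrays), bezafibrate 166 (299) and Wy-14643 35 (61). Without vehicle rat 1022 these were 1574, 478 and 59, and without vehicle rat 1061 bezafibrate called 103. Leaving out day 5 gave 147, 23 and 21, leaving out day 4 gave 153, 28 and 12, leaving out day 6 gave 368 for fenofibrate and 22 for Wy-14643, and leaving out day 3 gave 1239 for fenofibrate.

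The fibrates were compared directly, at doses that differ (400 and 250 mkd). In soleus fenofibrate exceeded bezafibrate in Acot1 by 1.05 ± 0.23, Ech1 by 0.68 ± 0.09, Acot2 by 0.55 ± 0.10, Acaa2 by 0.55 ± 0.11, Eci2 by 0.51 ± 0.07 and Hadha by 0.35 ± 0.07, and 7 of 16 mitochondrial beta-oxidation genes were higher (10 adjusted over the list alone; adjusted p = 0.00017 with an estimated correlation). It was lower than bezafibrate in Rbp7 by a log2 difference of -1.72 ± 0.17 and in Fabp4 by -0.56 ± 0.08. The difference called 109 genes and probes (478 without the doubted arrays, 404 without vehicle rat 1022), and 37, 315, 26 or 45 when day 2, 3, 4 or 5 was left out. The mean of the fibrates differed from Wy-14643 in 1 gene in soleus, Rbp7 (0.98 ± 0.15), named after its value was seen because so few passed. 13 passed without the doubted arrays, 4 without vehicle rat 1022 and 2 without vehicle rat 1034, and 3, 2, 0 or 4 without day 2, 3, 4 or 6, so that the call ended without day 4. Acot1 did not pass, with a difference of -0.04 and a 95% interval from -0.45 to 0.37, and Hadha had 0.08 with an interval from -0.04 to 0.19.

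In quad Acot1 led the rises as well. The mean of the PPARA agonists raised Acot1 by 1.21 ± 0.16 (n = 54 treated and 63 vehicle arrays), in 50 of 54 treated arrays, Acaa1b, a peroxisomal thiolase, by 0.65 ± 0.14, Pdk4 by 0.44 ± 0.09, Angptl4 by 0.36 ± 0.08, Ucp3 by 0.33 ± 0.07 and Ehhadh, the peroxisomal bifunctional enzyme, by 0.32 ± 0.07. Atp1b4 (0.38 ± 0.10) and Pik3c2g (0.37 ± 0.09) also rose. The largest falls were in Fras1 (-0.39 ± 0.10), Map3k6 (-0.35 ± 0.08), Rgcc (-0.34 ± 0.06), Ch25h, which makes 25-hydroxycholesterol (-0.32 ± 0.07), and Tob2 (-0.31 ± 0.08). Of 22 mitochondrial beta-oxidation genes 5 rose (9 adjusted over the list alone; adjusted p = 0.02 with an estimated correlation), with Acot2 at 0.28 ± 0.06, Eci1 at 0.19 ± 0.05, Hadh at 0.16 ± 0.04 and Hadha at 0.11 ± 0.03. Fuel switching and uncoupling had 3 of 11 higher (4 adjusted over the list alone; adjusted p = 0.02 with an estimated correlation). Peroxisomal beta-oxidation had 2 of 19 higher (4 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), and Cd36 rose by 0.26 ± 0.07. Cpt1b (0.07 ± 0.03), Cpt2 (0.03 ± 0.04) and Ppara (0.01 ± 0.03) did not pass. The mean called 155 of 18421 genes and probes, 44 higher and 111 lower. 486 passed without the doubted arrays and 557 without fenofibrate rat 1157 alone. Leaving out day 2, 3, 4 or 6 gave 254, 44, 62 or 67.

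In quad, fenofibrate raised Acot1 by 1.20 ± 0.22 (n = 18), Acaa1b by 0.76 ± 0.20, Fanca by 0.58 ± 0.15 and Eci1 by 0.40 ± 0.06, with 8 of 22 mitochondrial beta-oxidation genes higher (8 adjusted over the list alone; adjusted p = 0.4 with an estimated correlation). Lower were Fcrl2 (-0.57 ± 0.12), Slc25a30 (-0.54 ± 0.09), Ccl11 (-0.52 ± 0.14), and 3 of 18 fibroblast and matrix markers (5 adjusted over the list alone; adjusted p = 0.93 with an estimated correlation), among them Dcn (-0.50 ± 0.11). Angptl4 (0.09 ± 0.11) and Pdk4 (0.21 ± 0.12) did not pass, and without the doubted arrays Fanca (0.48) and Ccl11 (-0.30) did not pass either. Its count of 1048 rested on single arrays: it was 142 without fenofibrate rat 1157, whose values spread 7.7 times as widely as the median quad array, 1724 without vehicle rat 1068, and 197 without the doubted arrays. Leaving out day 2, 4, 5 or 6 gave 509, 442, 1816 or 34. Bezafibrate raised Rbp7 by 1.47 ± 0.16 (n = 20, higher in 19 of 20 arrays), Acot1 by 1.11 ± 0.21, Bmal1 by 0.85 ± 0.21, Angptl4 by 0.81 ± 0.11, Ucp3 by 0.62 ± 0.09, Pdk4 by 0.62 ± 0.12 and Fabp4 by 0.50 ± 0.10, and lowered Per1 (-0.60 ± 0.14), Fras1 (-0.55 ± 0.13) and Map3k6 (-0.52 ± 0.11). It called 300 genes and probes (278 without the doubted arrays, 146 without bezafibrate rat 1256, 544 without fenofibrate rat 1157), and 84, 95 or 132 without day 3, 4 or 5, and Fras1 (-0.40) did not pass without the doubted arrays. Wy-14643 called 3 genes: Acot1 (1.30 ± 0.24, n = 16), Ehhadh (0.56 ± 0.10) and the kinase Limk2 (-0.18 ± 0.03). 9 passed without the doubted arrays, 7 without fenofibrate rat 1157, 10 without day 2 and 0 without day 6.

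Fenofibrate minus bezafibrate in quad, again at unequal doses, gave -1.73 ± 0.20 for Rbp7, -0.72 ± 0.13 for Angptl4, -0.71 ± 0.12 for Fabp4 and -0.49 ± 0.12 for Ucp3, with 836 genes and probes called. The count depended on the doubted arrays: 36 passed without them and 38 without fenofibrate rat 1157, and leaving out day 2, 3, 4 or 6 gave 143, 1579, 390 or 42. The fibrate mean differed from Wy-14643 in quad in 1 gene, Rbp7 (1.05 ± 0.19), and in 1 without the doubted arrays, while none passed when day 4 or day 6 was left out. Acot1 had -0.14 with a 95% interval from -0.64 to 0.36. For Rbp7 against vehicle, looked up after these differences were seen, fenofibrate gave -0.19 ± 0.15 in soleus and -0.26 ± 0.17 in quad, and Wy-14643 gave -0.31 ± 0.16 and -0.44 ± 0.18, none of which passed.

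**Figure D2:**
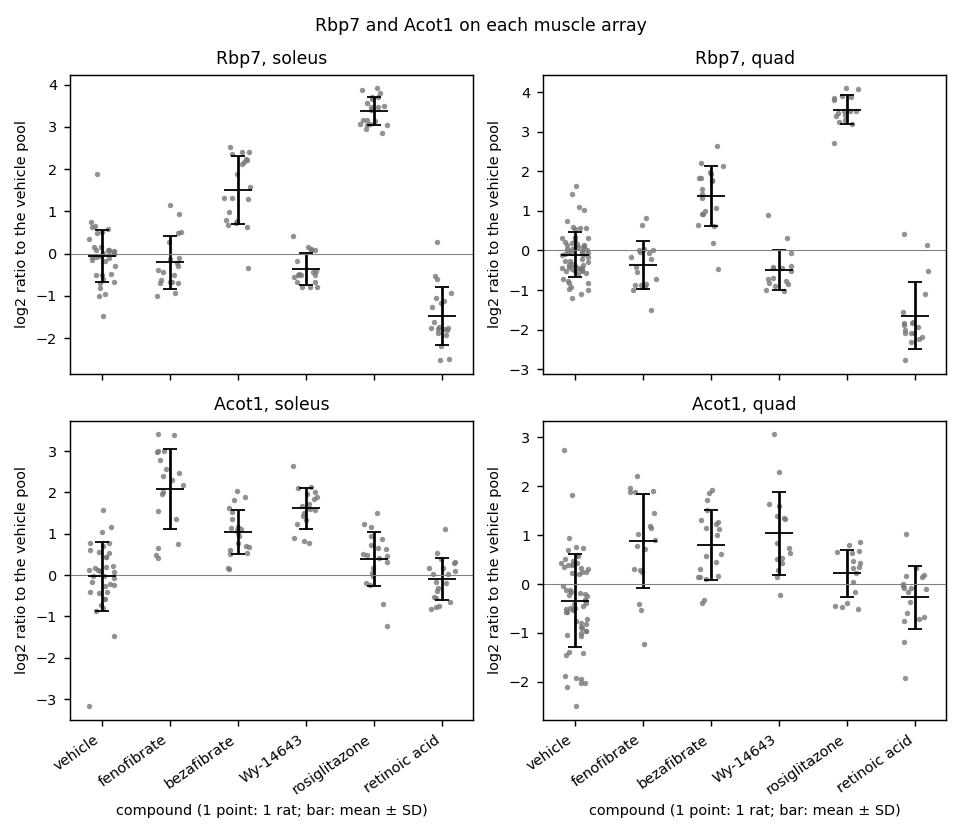
Log2 ratio to the vehicle pool of Rbp7 and Acot1 on each soleus and quad array, by compound; each point is 1 rat and the black bars are the mean and SD. In soleus the 20 bezafibrate arrays lay between -0.35 and 2.51 for Rbp7, and the 20 rosiglitazone arrays between 2.85 and 3.92.

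The series title speaks of a response that depends on fibre type. Soleus is known as a slow muscle and the thigh and EDL muscles as mostly fast, so the effects in soleus and quad were compared with a test of their difference. For the PPARA agonist mean, beta-oxidation genes rose more in soleus: Acot2 by 0.48 ± 0.10, Cpt2 by 0.31 ± 0.07, Acadvl by 0.30 ± 0.07 and Hadha by 0.21 ± 0.05, with 5 of 16 mitochondrial genes called (10 adjusted over the list alone; adjusted p = 0.018 with an estimated correlation). Ech1 (0.50 ± 0.08) and Eci2 (0.29 ± 0.06) also differed, as did Tmem171 (1.00 ± 0.16), Pik3c2g (0.77 ± 0.16), Gpam and Gpat3, which start glycerolipid synthesis (0.51 ± 0.11 and 0.51 ± 0.10), and Il1rl1 (0.50 ± 0.13). The effect was lower in soleus for Camk2b (-0.36 ± 0.09), Tmem54 (-0.27 ± 0.07), Jph2 (-0.25 ± 0.06), Tnpo2 (-0.19 ± 0.05) and Eid1 (-0.18 ± 0.04). Il1rl1 (0.31), Camk2b (-0.22) and Tnpo2 (-0.14) did not pass without the doubted arrays. With the rat as a block, over the 111 rats that gave both muscles, most of these named calls ended. Of these rats 28 had vehicle, while the fit without the block held 35 soleus and 63 quad vehicle arrays. Pairing and the loss of arrays cannot be told apart as the reason. Acot2 (0.39), Acadvl (0.35), Cpt2 (0.34), Hadha (0.16) and Eci2 (0.23) did not pass. Neither did Il1rl1 (0.47), Camk2b (-0.40), Tmem54 (-0.10), Jph2 (-0.25), Tnpo2 (-0.17) and Eid1 (-0.15). Angptl4 (0.55) passed. Over the mean and the single compounds, 20 of 43 calls of named genes ended with the block, and 17 with the block and without the doubted arrays. The difference without the block did not pass for Acot1 (0.42 ± 0.23), Pdk4 (0.27 ± 0.13), Angptl4 (0.53 ± 0.14), Ucp3 (0.16 ± 0.10), Cd36 (0.11 ± 0.10) or Ehhadh (-0.10 ± 0.13). 49 genes and probes passed, 43 of them higher in soleus, and 73 without the doubted arrays. With the rat as a block 34 passed, and 82 without the doubted arrays. The count was 90 without soleus vehicle rat 1022, 75 without quad vehicle rat 1068 and 29 without quad fenofibrate rat 1157, and 15, 9 or 22 without day 4, 5 or 6.

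Among single compounds, the tissue difference for fenofibrate included Tmem171 (1.25 ± 0.21), Pik3c2g (1.09 ± 0.22), Acot2 (0.84 ± 0.13), Angptl4 (0.67 ± 0.19), Cpt2 (0.45 ± 0.10) and Hadha (0.35 ± 0.07), and 9 of 16 mitochondrial beta-oxidation genes (12 adjusted over the list alone; adjusted p = 0.015 with an estimated correlation). That list had none of 18 genes called by limma for bezafibrate (0 adjusted over the list alone; adjusted p = 0.772 with an estimated correlation) or Wy-14643 (8 adjusted over the list alone; adjusted p = 0.0533 with an estimated correlation). Among single agonists it was thus called with an estimated correlation for fenofibrate only, with Wy-14643 close to the threshold. The agonists were not tested against each other here, and the list held 16 genes for fenofibrate and 18 for the others. Lower in soleus were Fanca (-0.81 ± 0.20), Ltb (-0.69 ± 0.18) and Camk2b (-0.53 ± 0.12). Without the doubted arrays Angptl4 (0.59), Ltb (-0.65) and Camk2b (-0.31) did not pass, nor did Ltb (-0.64) with the rat as a block. Its count of 978 fell to 155 without the doubted arrays, 134 with the rat as a block, 126 with both, 388 without soleus vehicle rat 1061 and 47 without quad fenofibrate rat 1157. It was 1958 without soleus vehicle rat 1022, 1978 without quad vehicle rat 1068, and 2884, 115, 116 or 28 without day 3, 4, 5 or 6. Bezafibrate differed in 9 genes and probes, the named ones being Tmem171 (0.95 ± 0.21), Gpat3 (0.66 ± 0.13) and Slc22a3 (0.66 ± 0.14). 10 passed without the doubted arrays and 11 with the block, Slc22a3 (0.65) not among them, and 1, 2 or 23 without day 3, 5 or 6. Wy-14643 differed in Ech1 alone (0.55 ± 0.11). 2 passed without the doubted arrays and 5 with the block, and 0 without day 3, 4 or 6.

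In liver the PPARA agonists moved 8373 of 18384 genes and probes, 3980 higher and 4393 lower (9059 without the doubted array, and 125 called by more than 2-fold). Genes of fatty acid oxidation were among the largest rises, with others: Acot1 rose by 3.11 ± 0.22 (n = 44 treated and 73 vehicle arrays; higher in 43 of 43 treated arrays with a value), Vnn1, a pantetheinase, by 2.77 ± 0.13, Ehhadh by 2.62 ± 0.12, Cpt1b, the carnitine acyltransferase typical of muscle, by 2.56 ± 0.09 and Ppp1r1a by 2.84 ± 0.17. The largest falls were in Tubgcp5 (-1.93 ± 0.14), the apolipoprotein Apoa4 (-1.78 ± 0.09), Nat8 (-1.41 ± 0.17), Fn3k (-1.36 ± 0.07) and Hes6 (-1.30 ± 0.12). Peroxisomal beta-oxidation had 14 of 17 genes higher and none lower (14 adjusted over the list alone; adjusted p = 2.4e-05 with an estimated correlation), with Ech1 at 1.36 ± 0.07 and Eci2 at 1.03 ± 0.04. Mitochondrial beta-oxidation had 17 of 19 higher (17 adjusted over the list alone; adjusted p = 2.5e-06 with an estimated correlation), with Acot2 at 1.62 ± 0.09, Cpt2 at 0.89 ± 0.05 and Hadha at 0.66 ± 0.03. Omega-oxidation and microsomal targets had 7 of 11 higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 0.00023 with an estimated correlation), among them Cyp4a1 (1.94 ± 0.09). Ketone body metabolism had 2 of 3 higher, Acat1 (1.34 ± 0.06) and the carrier Slc16a1 (0.79 ± 0.05), also adjusted over the list alone (adjusted p = 0.00023 with an estimated correlation).

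Fuel switching had 8 of 12 genes higher in liver (8 adjusted over the list alone; adjusted p = 0.0019 with an estimated correlation), with Pdk4 at 1.65 ± 0.08, and fatty acid uptake and lipid droplets 10 of 13 higher and 2 lower (the same adjusted over the list alone; adjusted p = 0.00023 with an estimated correlation), with Fabp3 at 1.65 ± 0.09, Cd36 at 0.73 ± 0.09 and Fabp2 at -1.25 ± 0.11. Lipogenesis had 8 of 14 higher and 4 lower (9 and 4 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation), with Scd at 1.93 ± 0.12 and Me1 at 1.54 ± 0.08. Gluconeogenesis and amino acid catabolism had 7 of 11 lower (7 adjusted over the list alone; adjusted p = 0.35 with an estimated correlation), with Pck1, the first committed enzyme of gluconeogenesis, at -1.11 ± 0.09 and G6pc1 at -0.72 ± 0.10. Bile acid and apolipoprotein genes had 7 of 14 lower and 1 higher (8 and 2 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -1.28 ± 0.21 and Apoc3 at -0.70 ± 0.07. Cell cycle genes had 15 of 23 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.35 with an estimated correlation), with Ccnb2 at 0.69 ± 0.08 and Cdk1 at 0.59 ± 0.08. Macrophage and leukocyte markers had 16 of 19 lower (16 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), with C1qb at -0.38 ± 0.04 and Csf1r at -0.35 ± 0.05, and 6 of 8 endothelial markers were lower (6 adjusted over the list alone; adjusted p = 0.35 with an estimated correlation). Ppara itself had -0.26 ± 0.06 and Ppargc1a -0.15 ± 0.04, both past 5%, and Cpt1a did not pass (-0.08 ± 0.06).

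Of the 19 mitochondrial beta-oxidation genes in liver, 17 rose with fenofibrate, 14 with bezafibrate and 17 with Wy-14643 (17, 16 and 17 adjusted over the list alone; adjusted p = 1.37e-05, 0.000484 and 1.82e-05 with an estimated correlation). Fenofibrate called 6814 genes and probes (7614 without the doubted array), with Ppp1r1a at 3.49 ± 0.26 (n = 14), Vnn1 at 3.04 ± 0.20, Ehhadh at 3.01 ± 0.18 and Hdc, which makes histamine, at 2.99 ± 0.19. Bezafibrate called 3910 (4657), with Acot1 at 3.20 ± 0.34 (n = 14), Gpat3 at 2.00 ± 0.27, Crot at 1.96 ± 0.21, Cyp7a1 at -2.79 ± 0.31 and Thrsp, a regulator of lipogenesis, at -1.23 ± 0.18. Wy-14643 called 7400 (8108), with Ppp1r1a at 3.67 ± 0.25 (n = 15), the aquaporin Aqp3 at 3.45 ± 0.24, Cpt1b at 3.25 ± 0.14 and Fabp3 at 2.75 ± 0.13. Fenofibrate minus bezafibrate called 3634 (4528, and 2303 without day 6). Fenofibrate was higher in lipogenesis, with 8 of 14 genes higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.012 with an estimated correlation): Scd by 2.44 ± 0.24, Thrsp by 1.53 ± 0.24, the transcription factor Srebf1 by 1.39 ± 0.10 and Acacb by 0.56 ± 0.07. The 3 Srebf1 probes ran from -0.06 to 2.68, with 2 of them higher, and the 2 Scd probes from 1.31 to 3.56. Cyp7a1 differed by 2.13 ± 0.40, and Cgref1 by -1.90 ± 0.26, Popdc2 by -1.77 ± 0.31 and Cyp26a1 by -1.69 ± 0.21 in the other direction. The fibrate mean minus Wy-14643 called 1660 (2211, and 1066 or 765 without day 5 or 6). Wy-14643 was higher in all 3 ketone body genes (3 adjusted over the list alone; adjusted p = 4.3e-05 with an estimated correlation), with Acat1 at -0.80 ± 0.10, and in Aqp3 (-1.97 ± 0.27), Fabp3 (-1.64 ± 0.15), Cpt1b (-1.03 ± 0.15) and Ucp3 (-0.50 ± 0.05). The doses differ in each of these comparisons.

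A change with time was tested as a slope per day over days 2 to 6. In liver 154 genes and probes passed, 63 with a rising and 91 with a falling effect (298 without rosiglitazone rat 1376; 8, 387 or 4 without day 2, 4 or 6). Scd2 rose by 0.52 ± 0.05 log2 units per day, Ppp1r1a by 0.46 ± 0.12, Insig1 by 0.44 ± 0.09 and Lpin1 by 0.24 ± 0.06, while Tubgcp5 (-0.41 ± 0.10) and Apoa4 (-0.35 ± 0.06) fell further. Cholesterol synthesis genes had 2 of 16 with a rising effect (4 adjusted over the list alone), among them Fdft1 (0.24 ± 0.06), with adjusted p = 7.9e-08, and adjusted p = 0.94 with an estimated correlation. In soleus and quad limma called 0, with 922 and 903 at an unadjusted p under 0.05. Without the doubted arrays the counts were 0 and 1.

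**Figure D3:**
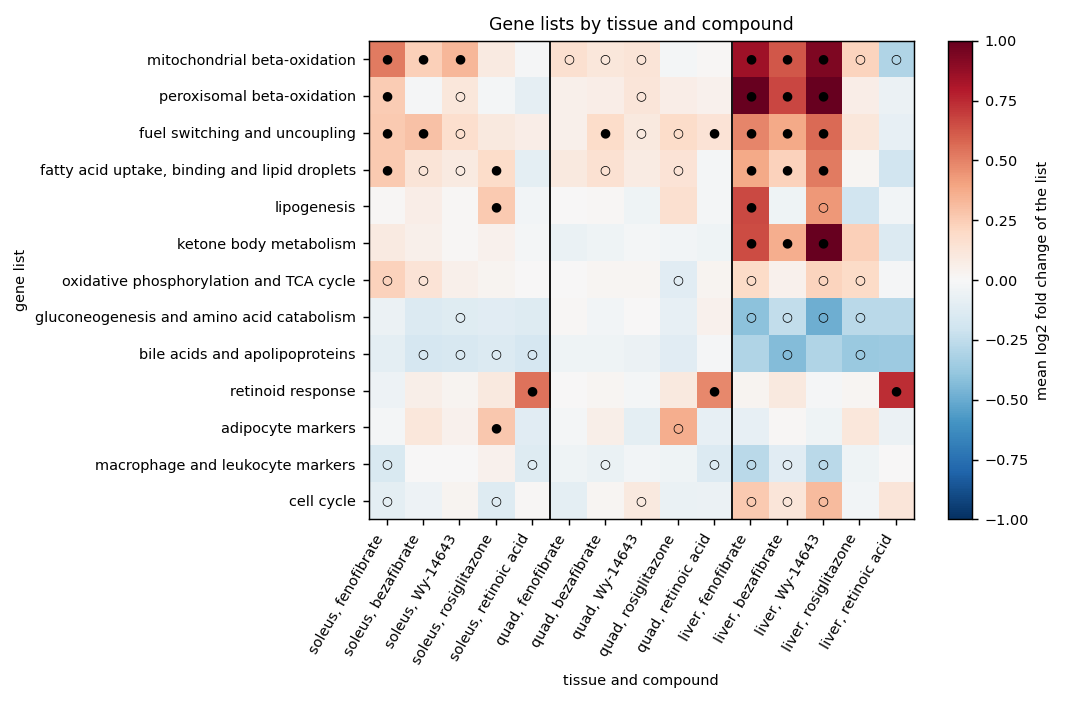
Mean log2 fold change of 13 gene lists for each compound and tissue; filled circles mark lists past 5% with an estimated correlation between genes and open circles those past 5% with the preset correlation only. Mitochondrial beta-oxidation reached the estimated-correlation call with all 3 PPARA agonists in soleus and liver, and with none of them alone in quad.

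With rosiglitazone the largest changes in muscle included single genes of endothelium and adipocytes. With an estimated correlation the endothelial list was called in neither muscle. The adipocyte list was called in soleus and not in quad, which is not itself a test of a difference between the muscles. Rbp7 rose by 3.40 ± 0.15 in soleus (n = 20) and 3.69 ± 0.18 in quad (n = 16), in every treated array of both muscles. Gpihbp1, which anchors lipoprotein lipase in capillaries, rose by 1.64 ± 0.08 and 1.70 ± 0.09, Fabp4 by 1.36 ± 0.08 and 1.36 ± 0.11, Fabp5 by 1.29 ± 0.13 and 1.53 ± 0.11, Kdr, a receptor of vascular endothelium, by 0.75 ± 0.08 and 0.92 ± 0.09, and Angptl4 by 1.09 ± 0.16 and 0.93 ± 0.12. The endothelial list itself was mixed: in quad 2 of 9 rose and 3 fell (2 and 4 adjusted over the list alone; adjusted p = 0.85 with an estimated correlation), with Pecam1 at -0.32 ± 0.07 and Emcn at -0.45 ± 0.10. Aqp1, a water channel of endothelium, fell by 0.77 ± 0.13 in soleus and by 1.43 ± 0.09 in quad, Prom1 fell by 0.61 ± 0.09 and by 0.75 ± 0.08, and Grm4 fell by 1.13 ± 0.28 and by 1.03 ± 0.20. In soleus 4 of 11 adipocyte markers rose (4 adjusted over the list alone; adjusted p = 0.0014 with an estimated correlation), among them Pparg (0.42 ± 0.07) and Aqp7 (0.38 ± 0.08). In quad 4 of 12 rose (4 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation), with Aqp7 at 0.80 ± 0.12. Lipogenesis in soleus had 3 of 14 higher (4 adjusted over the list alone; adjusted p = 0.031 with an estimated correlation): Scd (1.43 ± 0.19), Thrsp (0.85 ± 0.17) and Elovl6 (0.58 ± 0.08). The 4 Elovl6 probes ran from -0.07 to 1.03, with 3 of them higher, and the 2 Scd probes from 0.41 to 2.44.

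Rosiglitazone called 484 genes and probes in soleus (753 without the doubted arrays; 879 without vehicle rat 1022; 223 or 215 without day 4 or 5) and 1263 in quad (2224; 1939 without fenofibrate rat 1157; 592, 563 or 582 without day 3, 4 or 5). The tissue difference called 7, the named ones being Egln3 (-0.50 ± 0.11) and Olfml1 (-0.35 ± 0.07). 52 passed without the doubted arrays, 2 with the rat as a block, Egln3 (-0.43) and Olfml1 (-0.38) not among them, 22 without soleus vehicle rat 1022, and 21, 4, 3 or 1 without day 2, 3, 4 or 5. Aqp1 did not pass (0.65 ± 0.16) and passed without the doubted arrays (0.63). In liver rosiglitazone called 4162 (3420 without rosiglitazone rat 1376, 2577 without day 4), with Acot1 at 1.92 ± 0.32 (n = 15), Crot at 1.05 ± 0.21, Rbp7 at 0.99 ± 0.12, Lpl at 0.90 ± 0.15, Cyp7a1 at -1.34 ± 0.31 and Nat8 at -1.19 ± 0.25. 9 of 19 mitochondrial beta-oxidation genes were higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 0.47 with an estimated correlation). Rat 1376 had muscle markers 2.21 log2 units above the other liver arrays of its day, and the oxidative phosphorylation list, with 15 of 26 genes higher (16 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation), was not called without it (adjusted p = 0.14). Treated liver arrays ran from 0.11 to 4.64 for Rbp7 and from 0.18 to 4.8 for Lpl against vehicle, so high arrays raise these means. All 168 pairs of a named gene and a comparison in liver kept their side of the threshold without rat 1376. The sizes of the Rbp7 and Lpl effects without that rat are not given here.

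Retinoic acid raised the enzymes that degrade and store retinoids in all 3 tissues. Cyp26b1, which oxidises retinoic acid, rose by 4.02 ± 0.09 in soleus (n = 20), 4.01 ± 0.13 in quad (n = 18) and 4.93 ± 0.12 in liver (n = 15), in every treated array. Cyp26a1 rose by 2.37 ± 0.14, 1.88 ± 0.13 and 3.49 ± 0.16, and Lrat, which esterifies retinol, by 1.44 ± 0.12 in soleus and 2.17 ± 0.10 in quad. The receptor gene Rarb rose by 0.89 ± 0.06, 0.56 ± 0.05 and 0.83 ± 0.06. The retinoid response list had 6 of 18 higher and 1 lower in soleus (6 and 2 adjusted over the list alone; adjusted p = 1.3e-19 with an estimated correlation), 6 of 18 higher in quad (6 adjusted over the list alone; adjusted p = 1.1e-19 with an estimated correlation) and 6 of 17 higher and 1 lower in liver (the same adjusted over the list alone; adjusted p = 2.9e-19 with an estimated correlation). Rbp7 fell by 1.46 ± 0.15 in soleus and by 1.55 ± 0.17 in quad, Fabp4 fell by 0.30 ± 0.08 and by 0.42 ± 0.10, and Pparg fell by 0.28 ± 0.07, 0.27 ± 0.07 and 0.33 ± 0.07 from soleus to liver. In soleus Ccl2 (1.26 ± 0.26), Mmp9 (1.00 ± 0.16) and 2 of 16 genes of muscle damage and regeneration, Ncam1 (0.68 ± 0.10) and Runx1 (0.67 ± 0.15), also rose (5 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). In quad 4 of 19 macrophage and leukocyte markers fell (7 adjusted over the list alone; adjusted p = 0.07 with an estimated correlation), with Cd74 at -0.38 ± 0.07 and Lyz2 at -0.50 ± 0.10, while Trem2 rose by 0.89 ± 0.11.

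In liver retinoic acid lowered Cyp7a1 (-3.52 ± 0.31), Pla2g12a (-1.90 ± 0.11), Cyp17a1 (-1.70 ± 0.17), Alb (-1.53 ± 0.18) and Ppara (-0.74 ± 0.09), and 12 of 19 mitochondrial beta-oxidation genes (13 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation), with Acaa2 at -0.59 ± 0.10 and Cpt2 at -0.36 ± 0.07. Slc28a2 (2.61 ± 0.15) and Gria3 (2.40 ± 0.12) rose. Retinoic acid called 524 genes and probes in soleus (820 without the doubted arrays; 1066 without vehicle rat 1022; 192, 345 or 326 without day 4, 5 or 6), 445 in quad (636; 210 without day 4) and 5377 in liver (6065). The difference between soleus and quad called 13, among them Runx1 (0.74 ± 0.16), Junb (0.49 ± 0.11), Ngfr (0.43 ± 0.09), Selp (0.39 ± 0.09) and Ddit4l (-0.60 ± 0.14), and also Lrat (-0.73 ± 0.16), singled out after its value was seen. Without the doubted arrays Selp (0.33) did not pass. 26 passed without the doubted arrays, 47 with the rat as a block, Lrat (-0.60) not among them, 253 with both, and 26 without soleus vehicle rat 1022. Leaving out day 2, 3, 4, 5 or 6 gave 27, 21, 0, 3 or 4, so that without day 4 the call ended.

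Compounds that share vehicle rats also share chance values. Shared calls were therefore set beside simulated data in which the controls were shared and nothing changed, where no calls were shared. The noise in these sets was independent between genes and arrays, so few calls arise at all. The lack of shared calls there sets no baseline for the real arrays. In liver fenofibrate and Wy-14643 shared 5227 calls in the same direction and 6 in opposite directions, where independent lists would share 622 higher and 752 lower. Their effects correlated across genes, which are not independent replicates, at r = 0.905, against 0.165 in the simulated data and 0.884 with the vehicle arrays split between them. Bezafibrate and rosiglitazone shared 66 calls in soleus (50 higher, 16 lower, none opposite), against 2.01 and 0.443 for independent lists and 24 with the vehicle arrays split. In quad they shared 118 with 1 opposite, against 3.92 higher and 5.78 lower for independent lists and 50.3 with the split. The covariance of the bezafibrate and fenofibrate effects across genes in soleus was 0.0119, against 0.0034 in the simulated data. That noise has the same size on all arrays of a gene, so the share of shared controls is not settled. Such an excess was not particular to the PPARA agonists. In soleus bezafibrate and rosiglitazone had 0.0131 against 0.00343, and rosiglitazone and retinoic acid had 0.0096 against 0.00347. With the vehicle arrays split, r fell from 0.649 to 0.333, from 0.717 to 0.39 and from 0.501 to 0.207 for these pairs. The split also leaves fewer vehicle arrays per effect. In quad the covariance of bezafibrate and fenofibrate was 0.00129 against 0.00115, with r = 0.134 against 0.244. Fenofibrate and Wy-14643 had r = 0.043 against 0.222 there. With all arrays kept, among them fenofibrate rat 1157, the correlation of fenofibrate with each other agonist there did not exceed that of shared controls in the simulated data. Bezafibrate and Wy-14643 had r = 0.457 against 0.226. Fenofibrate and bezafibrate still shared 40 calls in quad with 1 opposite, against 2.06 higher and 7.24 lower for independent lists and 9.1 with the split. These correlations were not computed without the doubted arrays. The fenofibrate r between soleus and quad was -0.092 with those arrays and 0.362 without. A likeness of fenofibrate and the other agonists in quad thus stays open. Across tissues, the PPARA agonist mean shared 21 calls between soleus and quad, all in the same direction (15 higher and 6 lower, against 0.575 and 0.684 for independent lists; 38 without the doubted arrays, against 4.18 and 1.56), 182 between soleus and liver with 52 opposite, and 81 between quad and liver with 13 opposite (against 52.3 higher and 27.1 lower, and 9.06 higher and 26.6 lower, for independent lists). Without the doubted arrays these were 245, against 64.3 and 35, and 236, against 62.9 and 55.2. These add to 284, and to 519 without the doubted arrays. Rosiglitazone shared 268 calls between soleus and quad, none opposite, against 12.3 higher and 5.01 lower for independent lists. It shared 412 without the doubted arrays, against 27.7 and 18. Retinoic acid shared 166, none opposite, against 2.3 higher and 3.47 lower, and 261 without the doubted arrays, against 4.45 and 9.65. Independent lists leave out what tissues of the same rats share. With the means of compound and day subtracted, soleus and quad arrays of the same rat number correlated at a median of 0.246 over 111 rats. The median was 0.13 over 106 rats for soleus and liver, and 0.13 over 121 rats for quad and liver. No value that allows for this was computed.

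EDL was measured at lower doses and could be set only against the pool, without the spread of single controls. Rosiglitazone at 10 mkd gave ratios of 3.86 ± 0.15 for Rbp7 (n = 9), 1.57 ± 0.10 for Gpihbp1 and 1.47 ± 0.06 for Fabp4, each above 0 in 9 of 9 arrays and past 5% with limma. Retinoic acid at 2.5 mkd gave 3.16 ± 0.14 for Cyp26b1 (n = 11) and 0.95 ± 0.07 for Lrat. Cyp26a1 had 0.35 ± 0.14, above 0 in 5 of 11 arrays (limma, adjusted p = 0.0499), and did not pass against the other compounds (0.27) or without day 3 (0.30), 4 (0.27), 5 (0.46) or 6 (0.38). Acot1 passed with Wy-14643 at 10 mkd (0.86 ± 0.19, n = 12, above 0 in 10 of 12 arrays) and with bezafibrate at 25 mkd by limma (0.58 ± 0.22, n = 9), and did not with fenofibrate at 50 mkd (limma, 0.53 ± 0.22, n = 9, adjusted p = 0.0527). It also passed with retinoic acid at 2.5 mkd (0.77 ± 0.20, n = 11) and had 0.52 ± 0.22 with rosiglitazone at 10 mkd. Against the other compounds it passed with none of the PPARA agonists (0.24 for Wy-14643, -0.08 for bezafibrate and -0.14 for fenofibrate). That reference holds the other PPARA agonists as well. In a contrast added after these values were seen, the 3 agonists minus rosiglitazone and retinoic acid on days 4 to 6, Acot1 had -0.04 with a 95% interval from -0.44 to 0.36 and did not pass. That contrast called 23 genes and probes. Of 18603 genes and probes, limma called 6431 for fenofibrate, 6311 for bezafibrate, 8754 for Wy-14643, 6926 for rosiglitazone at 10, 7517 for retinoic acid and 6165 for rosiglitazone at 100. These counts hold what all EDL arrays share. Srsf5, for example, had 0.80 ± 0.05, 0.74 ± 0.05, 0.89 ± 0.04, 0.70 ± 0.05 and 0.86 ± 0.04 for the 5 low doses, and 3371 genes and probes were called in the same direction for all 5. Against the other compounds of the same days limma called 0, 0, 2, 122, 17 and 291 in the same order, with 1547 and 1070 for the fibrates at an unadjusted p under 0.05. No EDL array was in doubt. Leaving out day 6 gave 4162, 3319 and 4525 for fenofibrate, bezafibrate and rosiglitazone at 10. On day 4, rosiglitazone at 100 exceeded that at 10 in Aqp3 (1.06 ± 0.13, limma, n = 4 and 3) and in 1 unnamed probe, 1 of which passed without rosiglitazone rat 1345, 1348 or 1375. Acot1 differed by 0.79 ± 0.50, which did not pass.

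**Figure D4:**
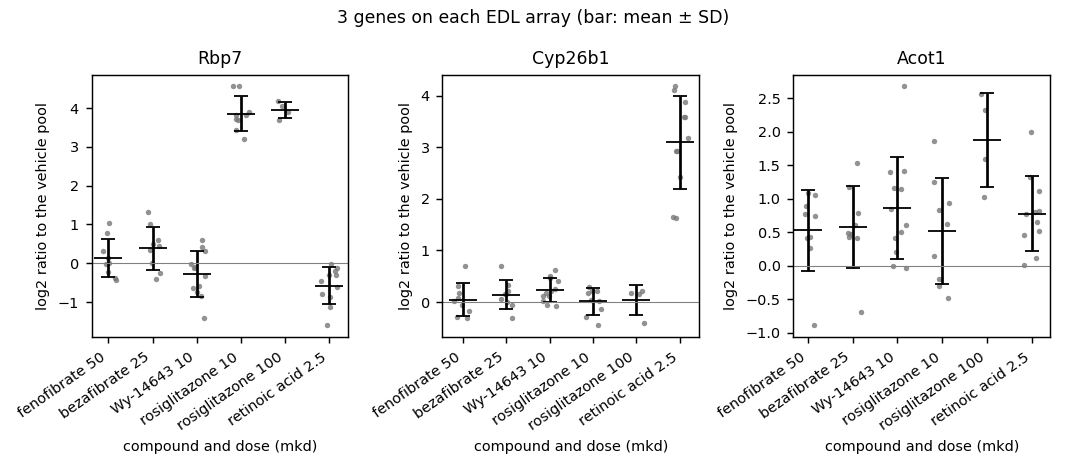
Log2 ratio to the vehicle pool of Rbp7, Cyp26b1 and Acot1 on each of the 54 EDL arrays, by compound and dose in mkd; points are rats and black bars are the mean and SD. The 9 arrays of rosiglitazone at 10 lay between 3.21 and 4.56 for Rbp7 and the 4 arrays at 100 between 3.69 and 4.18.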

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

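The test of the day 4 pool in soleus and both tests of the EDL ratios were chosen only after the result was seen. So were the splits that keep the muscles of a rat together. Array 1034 was singled out, and the doubted arrays were left out, after their values were seen. Among 13 pairs of a group and a gene in EDL, 2 had a rat far from the others, where chance gives about 1 in 20: Acot1 was -0.89 in fenofibrate rat 1131 and -0.68 in bezafibrate rat 1237.

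The effect of the PPARA agonists changed with the day for 154 genes and probes in liver. The effects in soleus and quad differed, by the test of the difference itself, for 49 with the PPARA agonist mean, 978 with fenofibrate, 9 with bezafibrate, 1 with Wy-14643, 7 with rosiglitazone and 13 with retinoic acid. The fenofibrate count was 155 without the doubted arrays, 134 with the replicate block and 47 without quad rat 1157. Chance could not be excluded from the counts for fenofibrate (6 of 100 splits), Wy-14643 (21), rosiglitazone (9) or retinoic acid (7). In splits that keep the muscles of a rat together it was excluded for retinoic acid (3) and not for fenofibrate (6), Wy-14643 (5) or rosiglitazone (8). In other splits, without the doubted arrays and with the muscles of a rat in separate groups, it was excluded for fenofibrate (4). There it was not for Wy-14643 (13), rosiglitazone (10) or retinoic acid (5). Among the genes named for the PPARA agonist mean, soleus exceeded quad in Tmem171 (1.00), Pik3c2g (0.77), Gpam (0.51), Gpat3 (0.51), Il1rl1 (0.50), Ech1 (0.50), Acot2 (0.48), Cpt2 (0.31), Acadvl (0.30), Eci2 (0.29) and Hadha (0.21). It lay below quad in Camk2b (-0.36), Tmem54 (-0.27), Jph2 (-0.25), Tnpo2 (-0.19) and Eid1 (-0.18). Of these 16 genes only Tmem171, Pik3c2g, Gpam, Gpat3 and Ech1 passed with the rat as replicate block, where the count was 34.

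Bezafibrate raised Rbp7 and Fabp4 in both muscles, as rosiglitazone did, while fenofibrate and Wy-14643 did not pass for Rbp7. An exchange of whole bezafibrate and rosiglitazone rats would place bezafibrate arrays at the rosiglitazone level. If near even, it would give an SD over 1.5. The SD of Rbp7 among the bezafibrate soleus arrays was 0.81. Their highest value (2.51) lay below the lowest rosiglitazone array (2.85). Together these values argue against an exchange of whole rats in soleus. A mixture within single samples would give values between the vehicle and rosiglitazone levels with a small SD. The test cannot tell such a mixture from an effect of bezafibrate, so it stays open. More adipocytes in the muscle would raise their abundant transcripts, but the adipocyte list without Fabp4 had a median of 0.07, with Plin1 at 0.10 ± 0.15, Cfd at 0.11 ± 0.27, Aqp7 at 0.26 ± 0.08 and Lipe at 0.20 ± 0.07, none past 5%, against 0.60 ± 0.08 for Fabp4, which argues against adipocytes as the whole source. A smaller share of adipocytes stays open, as does an action of bezafibrate at this dose on the targets of rosiglitazone, a hypothesis that was not tested.

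Soleus vehicle rat 1034 carried hepatocyte transcripts (Alb 2.61, Apoa1 3.11, Tat 3.36 on the log2 scale), and the other 28 soleus arrays of day 4 had a median of -2.38 over the hepatocyte genes, against -0.01 to -0.19 on other days. Liver RNA in this sample, which may then have entered the day 4 pool, is consistent with both. Whether array 1034 alone made the lower hepatocyte values after PPARA agonists cannot be told apart from a smaller remaining change, since the median without it was -0.06, between the bounds set in advance. No biological explanation was tested.

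In EDL 3371 genes and probes passed in the same direction, as ratios to the pool, with all 5 low-dose compounds. The mean ratios of these compounds correlated across genes, which are not independent replicates, at a median of 0.796 (0.707 to 0.852 over 10 pairs), which is consistent with an offset shared by all EDL arrays, from the dyes or the pool. Against the other compounds at most 1.54% of a compound's calls stayed, which argues against effects of single compounds as their source. A response common to all 5 compounds, or to dosing, stays open, because EDL has no arrays of single vehicle rats.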

How the results depend on the processing

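Leaving out the doubted arrays, together or singly, was chosen after the result was seen. Of 6469 values of a named gene under an alternative, 5910 kept their side of the threshold, 540 no longer passed, 16 newly passed and 3 turned. A value counted as turned only if its sign changed and it passed in either fit. Sign changes that passed in neither fit are among the 5910. Outside the slope, the largest rises and falls were chosen for the same sign on each day, so leaving out a day could not turn them. Complete values only left the estimates of the genes it kept unchanged. Those settings therefore say little about direction. Of 433 pairs of a named gene and a comparison past 5%, 10 no longer passed with array medians subtracted, 34 with arrays scaled and 31 with array weights. Of 43 such pairs in soleus minus quad, 20 no longer passed with the replicate block. The 3 that turned did so with other compounds as reference: Srsf5 in EDL with bezafibrate (-0.06) and rosiglitazone at 10 (-0.11), and Acot1 in EDL with bezafibrate (-0.08). Counts moved by more than 1.5 times under many settings, and the cause was not tested. Signal over background was not analysed here, so what it limits on weak probes is unknown.

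With arrays scaled to one spread the counts that moved were as follows. In soleus they were 595 for the PPARA agonist mean, 1016 for fenofibrate, 472 for bezafibrate, 62 for Wy-14643, 735 for rosiglitazone, 1086 for retinoic acid and 714 for fenofibrate minus bezafibrate. In quad they were 268 for the PPARA agonist mean, 58 for fenofibrate, 30 for Wy-14643, 1945 for rosiglitazone, 134 for fenofibrate minus bezafibrate and 3 for the fibrate mean minus Wy-14643. In liver they were 2670 for rosiglitazone and 31 for the day slope. For soleus minus quad they were 100 for fenofibrate, 14 for bezafibrate, 0 for Wy-14643, 32 for rosiglitazone and 39 for retinoic acid. In EDL they were 1 for rosiglitazone 100 minus 10. With array weights the counts that moved were as follows. In soleus they were 1243 for fenofibrate, 524 for bezafibrate, 131 for Wy-14643, 819 for rosiglitazone, 1081 for retinoic acid, 1579 for fenofibrate minus bezafibrate and 362 for the fibrate mean minus Wy-14643. In quad they were 285 for the PPARA agonist mean, 22 for fenofibrate, 571 for bezafibrate, 71 for Wy-14643, 4208 for rosiglitazone, 768 for retinoic acid, 11 for the day slope, 91 for fenofibrate minus bezafibrate and 16 for the fibrate mean minus Wy-14643. In liver they were 7482 for bezafibrate, 8376 for retinoic acid, 1083 for the day slope, 6717 for fenofibrate minus bezafibrate and 4149 for the fibrate mean minus Wy-14643. For soleus minus quad they were 399 for fenofibrate, 51 for bezafibrate, 53 for Wy-14643, 200 for rosiglitazone and 57 for retinoic acid. In EDL they were 9598 for bezafibrate 25. The estimate of the weights stopped before its tolerance was reached in some fits. Without the doubted arrays the counts that moved were as follows. In soleus they were 1114 for fenofibrate, 299 for bezafibrate, 61 for Wy-14643, 753 for rosiglitazone, 820 for retinoic acid, 478 for fenofibrate minus bezafibrate and 13 for the fibrate mean minus Wy-14643. In quad they were 486 for the PPARA agonist mean, 197 for fenofibrate, 9 for Wy-14643, 2224 for rosiglitazone, 1 for the day slope and 36 for fenofibrate minus bezafibrate. In liver they were 298 for the day slope. For soleus minus quad they were 155 for fenofibrate, 2 for Wy-14643, 52 for rosiglitazone and 26 for retinoic acid. The overlap between tissues was 519.

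With the ratio to the pool the PPARA agonist mean called 2696 in soleus and 3403 in quad, and day 6 minus day 2 called 8 in quad in place of the slope. With the rat as replicate block, soleus minus quad gave 134 for fenofibrate, 5 for Wy-14643, 2 for rosiglitazone and 47 for retinoic acid. With the replicate block and without the doubted arrays it gave 82 for the PPARA agonist mean, 126 for fenofibrate, 36 for bezafibrate, 14 for Wy-14643, 16 for rosiglitazone and 253 for retinoic acid. With other compounds as reference EDL gave 0 for fenofibrate (1547 at an unadjusted p under 0.05), 0 for bezafibrate (1070), 2 for Wy-14643, 122 for rosiglitazone at 10, 17 for retinoic acid and 291 for rosiglitazone at 100 by limma. Of 259 shifts of gene lists with the preset correlation, 55 were called with an estimated correlation.

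When single days or single doubted arrays were left out, or single arrays of rosiglitazone in EDL, the count moved within a range. In soleus it ran from 89 to 965 for the PPARA agonist mean, 147 to 1574 for fenofibrate, 23 to 478 for bezafibrate, 12 to 59 for Wy-14643, 215 to 879 for rosiglitazone, 192 to 1066 for retinoic acid, 0 to 0 for the day slope, 26 to 404 for fenofibrate minus bezafibrate and 0 to 4 for the fibrate mean minus Wy-14643. In quad it ran from 44 to 557 for the PPARA agonist mean, 34 to 1816 for fenofibrate, 84 to 544 for bezafibrate, 0 to 10 for Wy-14643, 563 to 1939 for rosiglitazone, 210 to 598 for retinoic acid, 0 to 0 for the day slope, 38 to 1579 for fenofibrate minus bezafibrate and 0 to 1 for the fibrate mean minus Wy-14643. In liver it ran from 7103 to 9059 for the PPARA agonist mean, 5351 to 7614 for fenofibrate, 2693 to 4657 for bezafibrate, 6029 to 8108 for Wy-14643, 2577 to 4372 for rosiglitazone, 3934 to 6065 for retinoic acid, 4 to 387 for the day slope, 2303 to 4528 for fenofibrate minus bezafibrate and 765 to 2211 for the fibrate mean minus Wy-14643. For soleus minus quad it ran from 9 to 90 for the PPARA agonist mean, 28 to 2884 for fenofibrate, 1 to 23 for bezafibrate, 0 to 1 for Wy-14643, 1 to 22 for rosiglitazone and 0 to 27 for retinoic acid. In EDL it ran from 6909 to 8118 for Wy-14643 10, 5690 to 7137 for retinoic acid 2.5, 4162 to 5521 for fenofibrate 50, 3319 to 6097 for bezafibrate 25, 4525 to 5799 for rosiglitazone 10, 1 to 3 for rosiglitazone 100 minus 10 and 4534 to 5949 for rosiglitazone 100.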

Other observations

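The splits without the doubted arrays, the splits that keep the muscles of a rat together, and which gene lists to describe here, were chosen only after the result was seen. In liver single genes of the clock and of drug metabolism passed. Their lists were not called with an estimated correlation, and 8373 of 18384 genes and probes passed in this tissue. With the PPARA agonist mean (n = 44), 7 of 13 circadian clock genes were lower and 1 higher (the same adjusted over the list alone; adjusted p = 0.371 with an estimated correlation), among them Dbp (-0.82 ± 0.18), Bhlhe41 (-0.72 ± 0.15) and Bhlhe40 (-0.55 ± 0.10). Of 24 drug metabolism genes 7 were higher and 7 lower (the same adjusted over the list alone; adjusted p = 0.971 with an estimated correlation), with Ces2c at 1.09 ± 0.13, Ugt1a1, which conjugates bilirubin, at 0.71 ± 0.07, Cyp1a2 at -0.93 ± 0.08 and Cyp2b3 at -0.45 ± 0.08. Proteolysis genes had 11 of 16 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.47 with an estimated correlation), with the proteasome subunits Psmd8 at 0.26 ± 0.04 and Psmc2 at 0.21 ± 0.04.

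Retinoic acid in liver (n = 15) lowered 11 of 24 drug metabolism genes and raised 5 (12 and 5 adjusted over the list alone; adjusted p = 0.961 with an estimated correlation), with Ugt2b1 at -1.27 ± 0.17, Abcc2, an export pump of the bile canaliculus, at -0.70 ± 0.10 and Cyp2c13 at 0.83 ± 0.08. It lowered 8 of 19 nuclear receptor genes and raised 2 (8 and 3 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation), among them Thrb (-0.46 ± 0.10) and the glucocorticoid receptor Nr3c1 (-0.44 ± 0.06), and 5 of 11 gluconeogenesis genes (5 adjusted over the list alone; adjusted p = 0.924 with an estimated correlation), with G6pc1 at -0.96 ± 0.15. Orm1, an acute phase protein, rose by 1.42 ± 0.18. Rosiglitazone in liver (n = 15) lowered 5 of 14 lipogenesis genes and raised 2 (the same adjusted over the list alone; adjusted p = 0.556 with an estimated correlation), with Thrsp at -0.85 ± 0.18 and Pklr, the liver pyruvate kinase, at -0.62 ± 0.12.

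Chance was weighed by drawing 100 splits of the arrays of each comparison, the real one included. It was called excluded where fewer than 5 of 100 splits reached the real count. No adjustment was made over comparisons or over kinds of split. Such a call concerns the number of genes and probes and not any single gene, so for a count of 1 it says little. In liver each real split called the most: 1 split of 100 reached 8373 for the PPARA agonist mean (highest other 5), 6814 for fenofibrate (7), 3910 for bezafibrate (1), 7400 for Wy-14643 (27), 4162 for rosiglitazone (2365), 5377 for retinoic acid (969), 154 for the day slope (1), 3634 for fenofibrate minus bezafibrate (198) and 1660 for the fibrate mean minus Wy-14643 (290), so chance can be excluded for each. In soleus it can be excluded for the PPARA agonist mean (360, 1 split, highest other 1), fenofibrate (612, 1 split, highest other 96), bezafibrate (166, 2 splits, highest other 1353), rosiglitazone (484, 2 splits, highest other 2109), fenofibrate minus bezafibrate (109, 1 split, highest other 0) and the fibrate mean minus Wy-14643 (1, 3 splits, highest other 1). From the count alone it cannot be excluded for Wy-14643 (35, 6 splits, highest other 1651) or retinoic acid (524, 5 splits, highest other 4511). That does not extend to single genes of retinoic acid in soleus: Cyp26b1 had 4.02 ± 0.09 and was higher in 20 of 20 arrays.

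In quad chance can be excluded for the PPARA agonist mean (155, 1 split, highest other 1), bezafibrate (300, 1 split, highest other 135), rosiglitazone (1263, 1 split, highest other 169) and retinoic acid (445, 1 split, highest other 29). It cannot be for fenofibrate (1048, 8 splits, highest other 7258), Wy-14643 (3, 15 splits, highest other 422), fenofibrate minus bezafibrate (836, 5 splits, highest other 2891) or the fibrate mean minus Wy-14643 (1, 16 splits, highest other 2718). For the difference between soleus and quad it can be excluded for the PPARA agonist mean (49, 1 split, highest other 2) and bezafibrate (9, 2 splits, highest other 9). It cannot be for fenofibrate (978, 6 splits, highest other 4191), Wy-14643 (1, 21 splits, highest other 416), rosiglitazone (7, 9 splits, highest other 1179) or retinoic acid (13, 7 splits, highest other 1260). These splits give the soleus and quad arrays of a rat separate groups, although 111 rats gave both and their arrays correlate. In 100 splits that keep the muscles of such a rat together, 3 reached the count for the PPARA agonist mean (highest other 507), 6 for fenofibrate (4253), 3 for bezafibrate (47), 5 for Wy-14643 (12), 8 for rosiglitazone (407) and 3 for retinoic acid (37). Chance was then excluded for the PPARA agonist mean, bezafibrate and retinoic acid. For the doses of rosiglitazone in EDL 7 of 35 splits called at least 2, with 7 the highest other. For the day slope limma called 0 in soleus (922 at an unadjusted p under 0.05) and 0 in quad (903), which each of 100 splits reaches whatever it calls (highest other 1 and 5121), so these splits say nothing about chance.

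Splits that called several times the real count, in soleus, quad and their difference, point to a structure of the samples, whose cause was not found. The splits keep tissue and day. Such splits also occurred without the doubted arrays: the highest other was 1866 for Wy-14643 in soleus (real 61), 1700 for fenofibrate in quad (197), 1933 for bezafibrate in quad (278) and 1270 for rosiglitazone in soleus minus quad (52). Chance could then not be excluded for bezafibrate (6 splits of 100) and retinoic acid (5) in quad. It could be excluded for retinoic acid in soleus (2), fenofibrate minus bezafibrate in quad (1), the fibrate mean minus Wy-14643 in quad (2) and fenofibrate in soleus minus quad (4).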
